A study of Rattus norvegicus with 24 samples.

How the data were processed

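The processed values of the series were used; raw array files were not used here. Per the labels, 5 µg of RNA of each organ went to a rat Affymetrix expression array. The processed values deposited by the authors are log10 intensities: read as log10, the values without the lowest and highest 1% span 2143-fold, and read as log2 it would span 10.1-fold. The base was inferred from this, and the way the authors summarised and scaled the probes is not given in the sources used here. Values were multiplied by log2(10), so that every change is a log2 change. No further scaling was applied, and blank cells, 77831 of 743520 (10.5%), were left missing. Blanks fall among dim probe sets: where 1 array is blank, the median intensity of the others is 32.2, against 104 over all values.

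The design had expected log2 values. A scale of log2(intensity + 16) with blanks at 0 was tried first, and its counts and those of the present scale were both seen before the return to the values without offset, as the design stated. That scale and offsets of 1 and 64 are given as alternatives chosen after seeing the data, as are the demand for at least 2 values per group, a batch term for the spleen arrays with over 1500 blanks, and a fit to the 8 spleen arrays with fewer. The batch term can be estimated only for genes with a value in 2005 and in 2001 or 2003; for the others the fit drops it, and calls among them are not corrected.

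Of 30980 probe sets, 20792 name a single gene, 436 several and 9752 none, giving 14201 genes, 4517 of them with over 1 probe set. For each gene the probe set with the highest mean of log2(intensity + 16) over 24 arrays was kept. A gene was tested where every group had at least 1 value: 12683 genes in liver, 13614 in spleen and 12474 in both. Of the untested, 413 genes in liver and 7 in spleen were blank on every array. Cyp2b1 and Cyp2b2 have no probe set that names them alone, and Cyp1a1 and Mki67 had too few liver values.

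R 4.3.3 and limma 3.58.1 were used. Each tissue was fitted with 4 group means over 12 arrays, and the tissue difference with 8 over 24, by lmFit, contrasts.fit and eBayes with a constant prior; p values were adjusted by Benjamini-Hochberg within a contrast at a threshold of 0.05. The drug effect is the mean of its effects without and with wood, the wood effect the mean of those in vehicle and drug, and the interaction the difference of the drug effects, with wood minus without. SE is that of the moderated fit, and SD that of 3 arrays. With 3 rats per group the number of arrays limits the precision.

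There were 38 gene lists, 32 tested in liver and 25 in spleen, written from general knowledge before the data were examined. They were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, on the 10799 liver and 12837 spleen genes with a value on every array, with p adjusted over the lists of a tissue and contrast. Named genes follow a rule set with the lists. It takes up to 10 rises and 10 falls per tissue with the same sign in both housings, up to 4 members of each list by size, and up to 5 genes per direction by p for wood and the interaction. It also takes 5 per direction by size for the tissue difference, 3 genes as values where none passes, and marker genes listed beforehand. Genes named by a locus number alone were passed over. Cfd in liver was chosen after its values were seen, as were Mmp2, Spic and the other genes drawn in the figures from among those named.

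Alternatives were quantile normalisation, median centring, genes at or above the median level, the mean of all probe sets of a gene, all probe sets, the fit of only the groups compared, eBayes with trend and robust, array weights, a change of at least 1.5-fold, leaving out each rat, and animals as replicate blocks. Labels were also reassigned within each housing or treatment for every count. The fit was tested on simulated data with 100 changed genes per size: a change of log2 1 was found in 57% of genes for the drug in liver and 82% in spleen, and one of log2 2 in 82% and 94%, with 0 calls where nothing was changed. For the interaction, log2 2 was found in 49% in liver and 69% in spleen, and for the tissue difference log2 1 in 55% and log2 2 in 86%. The simulated noise was independent between genes and arrays. The 0 calls therefore do not cover differences between whole arrays, such as that in blanks among the spleen arrays. The simulation was first run after the real fits.

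Liver and spleen of an animal share a number per the labels, and this was checked: across 10530 genes, the correlation of the deviations from the group mean between the liver and spleen of an animal ran from −0.058 to 0.170 and was above that with the other rats of its group in 11 of 12 animals, 2001 being the exception. No pair of arrays was identical. The labels give no time of tissue collection, body weight or blood count, and cell proportions were not analysed here.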

Results

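Cyclophosphamide is an alkylating cytostatic drug whose bifunctional metabolite crosslinks DNA, so that dividing blood-forming and lymphoid cells are its first targets. Here liver and spleen of 12 male Sprague-Dawley rats, 46 to 49 days old, were compared after 5 days of oral drug (40 mg/kg/day) or vehicle, each with or without wood sticks in the cage. There were 3 rats per group and 1 Affymetrix array per organ, 24 arrays in all. Each array carried 30980 probe sets. Liver arrays had 4924 to 6060 blank cells and spleen arrays 1021 to 1920, and the median intensity was 89.7 to 101 in liver and 113 to 121 in spleen. The highest correlation between a liver and a spleen array was 0.652. The liver array of animal 2003 (drug, no wood) had the most blanks, 6060, and a mean correlation of 0.847 with the other liver arrays, against at least 0.906 for each of the others.

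In liver, the drug lowered RNA of red cells and of antigen presentation, and that of some genes of resident macrophages. Alas2, the first enzyme of haem synthesis in red cell precursors, fell, as did the globin genes Hbb and Hba-a3. The class II invariant chain Cd74 and the class II genes RT1-Da, RT1-Ba and RT1-Db1 fell, and so did the complement gene C1qa and the receptor Csf1r, which mark Kupffer cells. Fewer genes rose, among them the glutathione transferase Gsta3, the chemokine Cxcl1, the inhibitor Id1 and the sterol synthesis enzymes Dhcr7 and Hsd17b7. In limma, 103 of 12683 tested genes passed an adjusted p of 0.05 between 6 drug and 6 vehicle rats (21 higher, 82 lower), and 1811 had an unadjusted p < 0.05. Of the 103, 15 were at least 1.5-fold higher and 73 at least 1.5-fold lower.

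Of the 8 MHC class II genes, 0 were higher and 4 lower in liver (0 and 7 when adjusted over the list alone), with a median log2 change of −1.28. Cd74 fell by 2.55 ± 0.15 (SE; adjusted p = 8.28e-05), from 10.32 ± 0.22 (SD) to 7.72 ± 0.38 without wood and from 10.35 ± 0.11 to 7.85 ± 0.28 with wood. RT1-Da fell by 2.18 ± 0.14 (adjusted p = 0.000101), RT1-Ba by 1.87 ± 0.18 (0.00287) and RT1-Db1 by 0.92 ± 0.16 (0.038). Of 16 erythroid genes, 0 were higher and 2 lower (0 and 4 over the list alone, median −0.40). Alas2 fell by 3.28 ± 0.15 (adjusted p = 1.14e-05), from 8.41 to 5.08 without and from 8.03 to 4.80 with wood. Hba-a3 fell by 3.94 ± 0.56 (adjusted p = 0.0194). Hbb stood at 13.24 and 12.89 in the vehicle groups and was blank on 2 of 3 arrays of each drug group, while the remaining array of each lies near the floor (0.30 in the group with wood), so that its log2 change of −12.17 (adjusted p = 4.51e-06) shows a large fall and not its size, which ran from −12.55 to −7.06 by setting. Of 16 macrophage genes, 0 were higher and 5 lower (0 and 9 over the list alone, median −0.61): C1qa fell by 0.96 ± 0.14 (adjusted p = 0.0221), Csf1r by 0.92 ± 0.12 (0.0159), Adgre1 by 0.94 ± 0.16 (0.0372), and Clec4f, a lectin of Kupffer cells, by 0.84 ± 0.14 (0.0341). The macrophage list is lost with an estimated correlation (adjusted p = 0.134), and of 12 refits without 1 rat Csf1r passes in 12, C1qa in 7, Clec4f in 4 and Adgre1 in 1. As single genes Jchain fell by 2.40 ± 0.40 (adjusted p = 0.038) and Ighvl1 by 2.21 ± 0.36 (0.0285), while the plasma cell list did not pass (camera adjusted p = 0.339). Slfn4, a gene of myeloid cells, fell by 1.93 ± 0.30 (adjusted p = 0.0237).

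**Figure D1:**
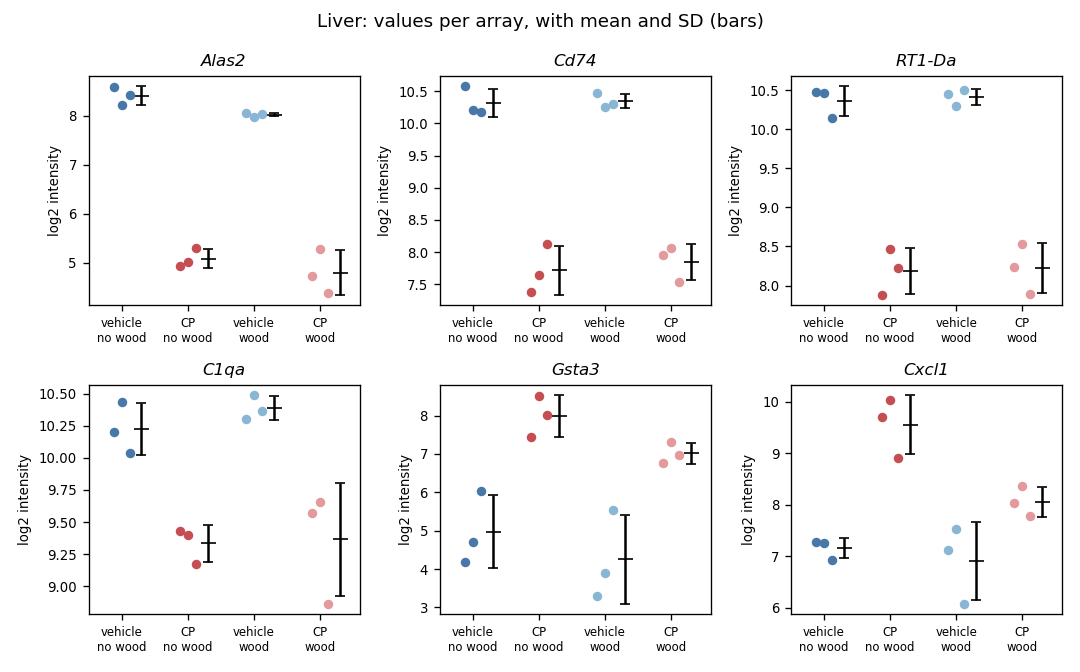
Log2 intensity of Alas2, Cd74, RT1-Da, C1qa, Gsta3 and Cxcl1 on the liver arrays of the 4 groups. Points are rats (3 per group), bars the mean and SD; Alas2 fell by 3.28 and Gsta3 rose by 2.89.

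Of 18 NRF2 targets, which answer electrophiles and oxidants, 1 was higher and 0 lower in liver (3 and 3 over the list alone): Gsta3 rose by 2.89 ± 0.43 (adjusted p = 0.0209; 3.01 without and 2.76 with wood), while Nqo1 stood at 0.94 ± 0.22 (0.0908). The list had a median of −0.02, a mean of 0.10 and a test direction of Down (camera adjusted p = 0.91). Of 17 cholesterol synthesis genes, 2 were higher and 0 lower (8 and 0 over the list alone, median 0.39). Dhcr7 rose by 0.94 ± 0.14 (adjusted p = 0.0197; 1.24 without and 0.64 with wood) and Hsd17b7 by 0.59 ± 0.08 (0.0187; 0.96 and 0.21). Cxcl1, which draws granulocytes, rose by 1.77 ± 0.27 (adjusted p = 0.0224), the thyroxine-binding globulin gene Serpina7 by 1.62 ± 0.25 (0.0224), Id1 by 1.03 ± 0.11 (0.00787) and the lymphocyte growth factor Il7 by 0.96 ± 0.12 (0.0159). Il7 is a call of 1 probe set: with the mean of all its probe sets its change was −0.42. Drug enzymes, sex-dependent genes and the growth hormone axis of the liver did not pass. Of 12 CAR and PXR targets, 8 male-predominant, 6 female-predominant and 10 growth hormone genes, 0 passed (0 in each over the list alone, median changes 0.20, −0.11, 0.28 and 0.01; the growth hormone genes had a mean of −0.17 and a test direction of Up), with Cyp3a23-3a1 at 0.04, Cyp1a2 at 0.14, Cyp2c11 at −0.17 and Igf1 at −0.05. Of 22 p53 targets 0 passed (1 and 0 over the list alone), with Cdkn1a at 0.44 ± 0.47 and Mdm2 at 0.09. Of 15 PPARα and fasting genes 0 passed, though 0 were higher and 11 lower when adjusted over the list alone (median −0.57; Fgf21 −2.61, Angptl4 −1.08, Plin2 −0.71). Of 23 interferon genes 0 were higher and 1 lower (0 and 10 over the list alone, median −0.45; Gbp2 −0.91 ± 0.17, adjusted p = 0.048).

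By camera with a preset correlation, the liver lists that moved down were MHC class II (adjusted p = 3.09e-11), macrophage (1.9e-09), interferon (7.56e-08), PPARα and fasting (1.76e-07), erythroid (0.000182) and B cell (0.0151, median −0.41, 0 members past the threshold, 0 and 2 over the list alone). Those that moved up were cholesterol synthesis (5.08e-09), acute phase (3.2e-05, median 0.10, 0 past, 2 and 0 over the list alone), the unfolded protein response (0.0151, median 0.27, mean 0.04, 0 past, 1 and 0 over the list alone) and mitosis (0.0224, median 0.27, 0 past, 0 and 0 over the list alone). Only MHC class II and erythroid hold with an estimated correlation (adjusted p = 0.0402 for each); for cholesterol synthesis it gives adjusted p = 0.114, for interferon and PPARα 0.252, for B cell 0.134, for acute phase 0.337, for mitosis 0.357 and for the unfolded protein response 0.479. The liver count rests on every vehicle rat: it was 35, 45 and 54 without 1001, 1003 and 1005, 42, 40 and 41 without 3001, 3003 and 3005, and 68 and 63 without the drug rats 4003 and 4005. Without 2003 it was 114, of which 79 are shared with the 103, and the counts lower were 3 for MHC class II, 1 for erythroid, 4 for macrophage and 0 for interferon. Of the 28 named liver genes past the threshold, Alas2, Cd74, RT1-Da, RT1-Ba, Csf1r, Id1 and Il7 passed in all 12 refits without 1 rat, and Hbb in the 10 where it has values, as it cannot be tested without 2003 or 4001. The other 20 lost the call at least once, with adjusted p up to 0.116 and the sign unchanged.

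In spleen, the drug took away the transcripts of red cell formation, B cells and dividing cells, and left a tissue richer in those of stroma, vessels and red pulp macrophages. Ahsp, Alas2 and Hemgn of red cell precursors were among the largest falls, with the B cell receptor chain Cd79b, the B cell antigen Ms4a1 and the adaptor Blnk. Markers of proliferation such as Mki67 and Cenpf fell, while the p53 targets Cdkn1a and Phlda3 rose. The red pulp regulator Spic, the scavenger receptor Cd163 and the matrix protease Mmp2 rose. In limma, 7485 of 13614 tested genes passed between 6 drug and 6 vehicle rats (3660 higher, 3825 lower), and 8168 had an unadjusted p < 0.05; 90 were at least 4-fold higher and 174 at least 4-fold lower.

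Of 19 erythroid genes, 0 were higher and 18 lower in spleen (the same counts over the list alone, median −3.67). Ahsp, the chaperone of free alpha globin, fell by 6.71 ± 0.33 (adjusted p = 4.51e-07), Alas2 by 6.65 ± 0.19 (4.21e-08, with −7.17 without and −6.13 with wood), Hemgn by 5.89 ± 0.25 (2.47e-07) and the carbonic anhydrase Car2 by 5.01 ± 0.16 (6.45e-08). The driver Klf1 fell by 3.25, Gata1 by 2.61 and the transferrin receptor Tfrc by 2.29, while Epor stood at −0.12 (0.45). Of 13 B cell genes, 0 were higher and 13 lower (the same over the list alone, median −3.26). Cd79b fell by 5.20 ± 0.29 (adjusted p = 8.64e-07), from 11.68 to 6.87 without and from 11.96 to 6.37 with wood. Ms4a1 fell by 5.10 ± 0.30 (1.19e-06), Fcer2 by 4.25 ± 0.24 and Blnk by 3.97 ± 0.11 (4.21e-08). Of 6 plasma cell genes 0 were higher and 4 lower (the same over the list alone, median −0.70), with Mzb1 at −2.95 ± 0.13 (2.92e-07) and Jchain at −0.89. Of 35 mitosis genes 0 were higher and 33 lower (the same over the list alone, median −1.40): Cenpf fell by 2.90 ± 0.27 (adjusted p = 1.27e-05), and Mki67 by 2.39 ± 0.24 (2.22e-05). Ccnb2 stood at −2.36 ± 0.23. Of 29 replication genes 0 were higher and 22 lower (the same over the list alone, median −0.64; Mcm3 −1.58 ± 0.12, 3.14e-06; Dut −1.07). Of 13 platelet genes 0 were higher and 12 lower (0 and 13 over the list alone, median −1.53), among them Nfe2, shared with red cell precursors, at −4.52 ± 0.21 (3.45e-07) and Tubb1 at −2.92 ± 0.20.

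Of 12 granulocyte genes, 1 was higher and 8 lower in spleen (1 and 9 over the list alone, median −1.67). The defensins RatNP-3b and Np4 fell by 6.04 ± 0.40 (adjusted p = 2.04e-06) and 5.00 ± 0.36, and Camp by 3.38 ± 0.41, all granule genes of maturing neutrophils. S100a9 fell by 1.99 ± 0.51 (0.00767), while the receptor Cxcr2 rose by 0.60 (0.0059). Of 24 interferon genes, 2 were higher and 16 lower (2 and 17 over the list alone, median −0.51): Rsad2 fell by 5.62 ± 0.54 (1.7e-05) and Mx2 by 1.42 (0.00101), and Gbp2 rose by 1.15 ± 0.08 (2.76e-06) and Cxcl10 by 0.80 (0.0074). T cell genes were mixed, 3 higher and 9 lower of 20 (3 and 10 over the list alone, median −0.32), with Cd4 up by 1.16 (adjusted p = 3.21e-05), Lef1 down by 0.74, Cd3e at −0.18 (0.357) and Cd8a at 0.05 (0.728). Of 15 NK cell genes 1 was higher and 7 lower (the same over the list alone, median −0.27; Eomes −0.92), and of 8 MHC class II genes 0 and 5 (the same over the list alone, median −0.24), with the regulator Ciita down by 1.10 ± 0.08 and RT1-Da by 0.30 ± 0.08 (0.00806). With the division of the spleen arrays by blanks as a batch term 3 class II genes are lower, as RT1-Ba (adjusted p = 0.124) and RT1-Db1 (adjusted p = 0.0523) lose their calls. Without 1 rat these pass in 6 and 4 of 12 refits. In this tissue 7485 of all 13614 tested genes passed. The counts of T cell, NK cell and class II genes therefore do not by themselves set those lists apart. Other large falls were the sulphotransferase Chst1 at −6.54 ± 1.02 (0.000389) and the red cell antigen Xk at −5.30 ± 1.55 (0.017), which has blanks and stood at −2.75 without 2003 or with the blank division as a batch term, −7.85 without 2005 and −1.03 with an offset of 64.

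Of 23 p53 targets, 15 were higher and 1 lower in spleen (the same over the list alone, median 0.40). Cdkn1a, which halts the cell cycle, rose by 3.51 ± 0.14 (adjusted p = 7.9e-07). With wood, where every array has a value, it rose by 2.22, from 6.61 ± 0.22 to 8.83 ± 0.23. The 4.81 without wood rests on a vehicle level of 3.77 from 1 array, the other two being blank. Phlda3 rose by 1.31 ± 0.09 (3.05e-06), Plk2 by 1.31 ± 0.10 and Gdf15 by 1.11 ± 0.19 (0.000844), while Sesn1 fell by 0.62 and Mdm2 stood at 0.10 (0.2). Of 16 macrophage genes, 13 were higher and 1 lower (14 and 1 over the list alone, median 0.82): Spic rose by 1.39 ± 0.08 (8.19e-07), Mrc1 by 1.20, Cd163 by 1.18 and Cd68 by 1.18 ± 0.06 (4.34e-07) and C1qa by 0.48 ± 0.09 (0.000952), and Lyz2 fell by 1.08. Of 19 stroma genes 14 were higher and 1 lower (14 and 2 over the list alone, median 1.01), with Mmp2 up by 2.09 ± 0.09 (2.38e-07), Postn by 1.85 ± 0.14 and Pdgfra by 1.40, and Fn1 down by 1.06. Of 13 endothelial genes 12 were higher and 1 lower (the same over the list alone, median 0.91), with Lyve1 up by 1.29, Emcn by 1.05 ± 0.07 and Vwf down by 0.77 (0.002). Of 16 clock genes 9 were higher and 3 lower (the same over the list alone, median 0.72): Per3 rose by 2.05 ± 0.35 (0.000749), Dbp by 1.61 and Nr1d1 by 1.49 ± 0.13, and Cry1 fell by 1.22. Of 12 glucocorticoid targets 5 were higher and 0 lower (the same over the list alone, median 0.58; Errfi1 1.81 ± 0.38, Sgk1 0.98). The growth factor Pdgfc rose by 3.08 ± 0.16 (6.91e-07; 4.59 without and 1.56 with wood).

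The largest rises by size come from genes with low or blank values in a vehicle group. They include Col23a1 at 4.46 ± 1.43 (adjusted p = 0.0254; 8.04 without and 0.89 with wood), Krt79 at 4.40 ± 0.43 (6.14 and 2.66), Cacna1g at 3.87 (6.89 and 0.86), Hfe at 3.71 ± 0.86 (6.64 and 0.78) and Arhgef5 at 3.56 (0.72 and 6.41). With an offset of 64 and blanks at 0 they shrink, Krt79 to 0.39, Cacna1g to 0.50, Hfe to 1.26 and Arhgef5 to 0.38. Col23a1 does not pass without 2001 or 2003 (adjusted p = 0.0529 for each) nor with the division of the spleen arrays by blanks, described further on, as a batch term (adjusted p = 0.115). Of 12 exocrine pancreas genes 1 was higher and 0 lower (the same over the list alone, median 0.97), Cela1 at 2.60 ± 0.53 (0.00364), with Prss1 at 1.65 ± 0.95 (0.168). Cela1 is blank in 1001 and 1003, so that its level in vehicle rats without wood rests on 1 array. The pancreas transcripts were highest in the spleen of 2003, with Prss1 at 11.61 there. Of 11 hepatocyte genes 0 passed (0 over the list alone, median −0.11; Alb −0.55).

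**Figure D2:**
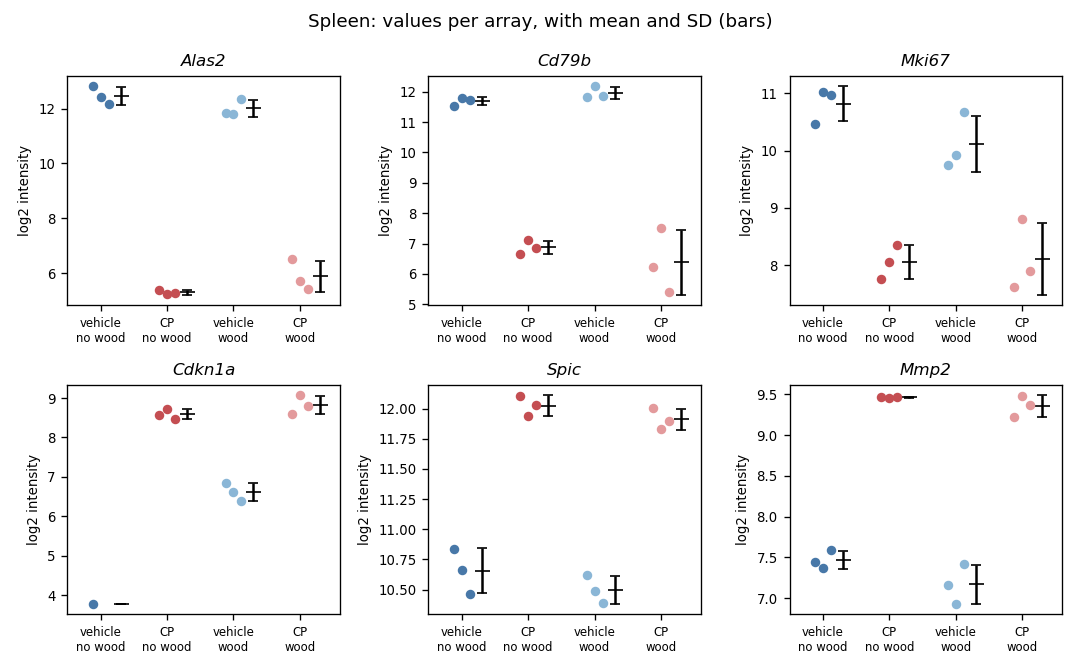
Log2 intensity of Alas2, Cd79b, Mki67, Cdkn1a, Spic and Mmp2 on the spleen arrays of the 4 groups. Points are rats (up to 3 per group, blanks not drawn), bars the mean and SD; Alas2 fell by 6.65 and Mmp2 rose by 2.09.

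By camera with a preset correlation, erythroid and B cell (adjusted p = 1.13e-09 each), mitosis (3.6e-09), replication (1.32e-05), platelet (1.8e-05), interferon (0.0124), granulocyte (0.019) and plasma cell genes (0.0428) moved down in spleen. Stroma (9.12e-06), macrophage (1.8e-05), endothelial (8.81e-05), p53 (0.000829) and clock genes (0.0428) moved up. None of them holds with an estimated correlation, the smallest being adjusted p = 0.176, in a tissue where most tested genes passed. By fry, erythroid (2.29e-07), B cell (2.65e-08), mitosis (0.000201), p53 (1.36e-06), macrophage (7.59e-07) and stroma (2.69e-07) passed. This test asks whether the genes of a set move one way on balance and does not compare them with genes outside it. In this tissue a pass therefore does not set a list apart from the other genes. The spleen arrays also differ in blanks: 1001, 1003 and 1005 (vehicle, no wood) and 2005 (drug, no wood) have 1778, 1908, 1920 and 1798, the other 8 from 1021 to 1183. The term can be estimated only where 2005 and a rat of its group on the other side have values, and so rests on 1 array. With that division as a batch term 6660 genes pass, 6082 of them among the 7485, and the term could be estimated for 5946 of those shared. The higher and lower counts are 0 and 18 for erythroid, 0 and 13 for B cell, 0 and 32 for mitosis, 12 and 1 for p53 and 14 and 1 for stroma, but 3 and 3 for T cell genes.

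**Figure D3:**
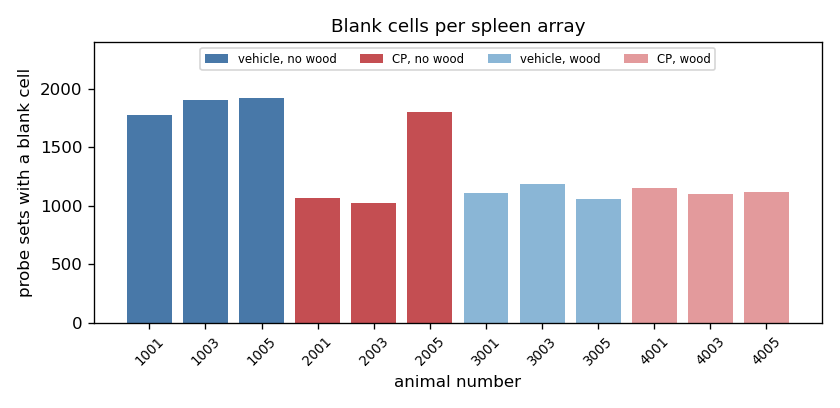
Number of probe sets with a blank cell on each of the 12 spleen arrays, by animal number and group. The 4 arrays on the high side run from 1778 to 1920, the other 8 from 1021 to 1183.

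The drug response was compared between the housings, and in spleen most genes called without wood were called with it too. In spleen 6140 genes passed without wood (3097 higher, 3043 lower, 7235 at an unadjusted p < 0.05) and 5228 with wood (2706 and 2522; 6353), and 4030 passed in both against 2358 expected from the sizes. The expected number takes the calls as independent, although both contrasts share an estimate of the spread per gene from a single fit. Of the 6140, 5711 (93.0%) had the same sign with wood. Across genes, which are not independent replicates, the 2 effects had r = 0.639 over all genes and 0.909 over the 6807 genes at or above the median level. With the blank division as a batch term the count without wood is 3794, of which 3346 are shared, 3211 of them where the term could be estimated. In liver 19 genes passed without wood (7 higher, 12 lower, 1512 at an unadjusted p < 0.05) and 6 with wood (0 and 6; 1030), and all 6 with wood were among the 19. Of the 19, 16 had the same sign with wood. Across liver genes r was 0.155 over all and 0.568 over the 6342 genes at or above the median. In refits without 1 rat, the liver count without wood was 12 without 1005, 11 without 2003, 29 without 2005 and 32 without 4005. The count with wood ran from 4 to 8 in these refits. Other settings moved both counts further, as given in the part on processing.

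Sterol synthesis genes in liver moved up with the drug where no wood was given, and whether wood changed this was tested by the interaction. The 17 cholesterol genes had a median of 0.85 without wood (camera adjusted p = 3.31e-14; adjusted p = 0.0523 with an estimated correlation) and 0.05 with wood (adjusted p = 0.441). The interaction gave a median of −0.75 (camera adjusted p = 2.22e-12), which does not hold with an estimated correlation (adjusted p = 0.13) nor by fry (adjusted p = 0.0556). In it 0 members passed, 0 higher and 5 lower when adjusted over the list alone. The interaction of wood and drug in liver called 0 genes in limma (650 at an unadjusted p < 0.05, smallest adjusted p 0.0948), and 0 under every other setting apart from refits without 1 rat (0 to 1). Its smallest values were those of the eosinophil peroxidase gene Epx at 7.60 (adjusted p = 0.0948), which rests on 1 value in the drug group without wood, and of Tom1l1 at 1.44 (0.128). Lipogenesis (median −0.38; camera adjusted p = 0.0015) and immediate early genes (−0.52; 0.0015) moved down and PPARα genes up (0.19; 0.0278) in the interaction, and none of these holds with an estimated correlation (adjusted p = 0.145, 0.428 and 0.724).

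Wood alone left the liver without a called gene. In limma 0 of 12683 genes passed for wood over both treatments (781 at an unadjusted p < 0.05), 0 in vehicle rats (484) and 0 in drug-treated rats (984). Other settings gave 0 to 1, 0 to 3 (3 without 1003) and 0 to 4 genes (4 without 2001 or 4001). The smallest adjusted p values were 0.163 for Epx (3.59 ± 0.38), Xxylt1 (2.84) and Rapgef5 (−0.97), 0.109 for Xxylt1 in vehicle (5.03) and 0.0507 for Epx in drug-treated rats (7.39). Acat2, which makes acetoacetyl-CoA for sterols, stood at −1.33 in drug-treated rats (adjusted p = 0.0919). For wood over both treatments cholesterol synthesis moved down by camera (median −0.26; adjusted p = 2.52e-07; 0 members past, 0 and 1 over the list alone), as did lipogenesis (−0.14; 0.0328); neither holds with an estimated correlation (adjusted p = 0.427 for each). On simulated data, liver changes of log2 1 were found in 45% of genes for the drug with wood, also a contrast of 3 rats against 3, and in 21% for the interaction, and those of log2 2 in 80% and 49%. The drug over both housings has the same form as wood over both treatments. It gave 57% at log2 1 and 82% at log2 2. Changes of log2 1 would often be missed in all of these contrasts, and those of log2 2 also in the interaction.

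Wood went with many gene differences in spleens of vehicle rats and with 0 called genes in drug-treated rats. The genes with the smallest p share no evident function. The tRNA deaminase subunit Adat3, the testis poly(A) polymerase Papolb and the membrane gene Tmem239 were higher with wood. The hedgehog pathway gene Smo and the signalling inhibitor Spry2 were lower. Of 13614 genes, 2058 passed in vehicle rats (1018 higher, 1040 lower; 4624 at an unadjusted p < 0.05) and 0 in drug-treated rats (1173, smallest adjusted p 0.0976, and 0 to 12 by other settings, 4 and 11 without 2003 and 2005), and over both treatments 1647 passed (823 and 824; 4418). In vehicle rats Tmem239 rose by 4.15 ± 0.15 (adjusted p = 9.84e-06; 3.55 to 7.70), Adat3 by 6.19 and Papolb by 5.15, and Smo fell by 1.45 ± 0.12 (0.00032; 6.40 to 4.95) and Spry2 by 1.26 (0.000424). Adat3, Papolb and Ranbp17 (7.89) are blank on 2 of 3 arrays of the vehicle group without wood, so that each rests on 1 array there. With an offset of 64 and blanks at 0 their values were 2.22 for Adat3, 0.82 for Papolb and 1.21 for Ranbp17, and Tmem239 lost its call with an offset of 1 (adjusted p = 0.111). Smo turns with the probe set: the mean of its probe sets gave 0.065. In drug-treated rats Cym stood at −2.54 (adjusted p = 0.0976) and Slc7a6 at −0.91 (0.186). No list passed for wood over both treatments by camera (smallest adjusted p 0.122); 5 of 23 p53 targets were higher and 1 lower (6 and 1 over the list alone).

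These wood counts move with the division of the spleen arrays by blanks. All vehicle rats without wood lie on the high side and all with wood on the low side. With the division as a batch term 220 genes pass for wood in vehicle, 128 of them among the 2058, and 108 for wood over both treatments, 70 among the 1647; 1 p53 target is then higher and 0 lower. Only 35 of those 128 and 19 of those 70 are genes for which the term could be estimated, out of 1924 and 1542 such genes called without it. Tmem239, Adat3, Papolb and Ranbp17 are blank in 2005 as well, so the term does not act on them and their wood effect was not tested against the division. Smo (−1.79) and Spry2 (−1.03, adjusted p = 0.0338) pass with the term, and Ppp1r14c (−1.42 in vehicle) does not (adjusted p = 0.0556). The vehicle count was 1297, 925 and 1009 without 1001, 1003 and 1005, 977, 786 and 1152 without 3001, 3003 and 3005, and 3277 without 2005, the drug rat on the high side. The count over both treatments was 812, 994, 931, 712, 964, 868 and 654 without 1003, 1005, 3001, 3003, 3005, 4003 and 4005.

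The interaction of wood and drug in spleen called 96 genes (20 higher, 76 lower; 1770 at an unadjusted p < 0.05), 58 of them at least 4-fold lower. A positive value means that the drug's effect was higher with wood. The interaction includes the wood contrast in vehicle, which coincides with the division of the spleen arrays by blanks. The batch term could be estimated for 53 of the 96 genes. Spry2 stood at 1.49 ± 0.16 (adjusted p = 0.00298), Smo at 1.40 (0.00573), Col6a6 at 1.23 and the chromatin gene Cbx7 at 1.27. On the other side were Adat3 at −5.91 ± 0.20 (0.000132), Papolb at −5.09, Tmem239 at −3.98, Ranbp17 at −8.21 and the channel Kcnk2 at −6.89, genes with blanks in the groups without wood. All 5 lose the call with each offset and blanks at 0, with adjusted p up to 0.389, 0.433, 0.823, 0.378 and 0.438 and changes down to −1.54, −0.53, −1.06, −0.98 and −2.03. Smo loses its call with the mean of its probe sets (0.11, adjusted p = 0.933) and with an offset of 64 (0.61, adjusted p = 0.0674). By camera erythroid (median 0.90; adjusted p = 3.01e-06), replication (0.50; 0.000206), mitosis (0.59; 0.000467) and NK cell genes (0.28; 0.0137) moved up and macrophage genes down (−0.18; 0.0129), with 0 members past the threshold; none holds with an estimated correlation (adjusted p = 0.827 for each). The count was 1013 without 2005, 45 to 48 without 2001, 2003 or 3003, 57 and 59 without 4001 and 4003, and 62 without 3001 or 4005. It was 173 with the batch term, of which 68 are shared, 25 of them where the term could be estimated. For Adat3, Papolb, Tmem239, Ranbp17 and Kcnk2 the term could not be estimated. Their interaction was thus not tested against the division.

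The drug's effect differed between liver and spleen in 4129 of 12474 genes tested in both (1836 with the liver effect higher, 2293 lower; 5296 at an unadjusted p < 0.05). The B cell gene Cd79b, the red cell gene Ahsp and the defensin RatNP-3b fell in spleen, and in liver did not pass (1.47, −1.02 and 0.00), while several macrophage genes moved in opposite directions. Liver minus spleen was 6.67 ± 0.80 for Cd79b (adjusted p = 2.63e-05), 6.04 ± 0.60 for RatNP-3b (2.01e-06), 5.69 ± 0.64 for Ahsp (1.01e-05) and 7.37 ± 1.47 for Chst1 (0.00152). It was 8.32 ± 0.58 for the granzyme Gzmm (1.71e-06), whose liver values are blank on 2 of 3 arrays in 3 of the groups; with blanks at 0 it was 1.58 (0.0936) with an offset of 16, 2.13 (0.367) with 1 and 1.12 with 64. On the other side were Hbb at −7.93 (4.77e-06), a size that rests on near-floor liver values and ran from −8.53 to −3.05 by setting, the chemokine Cxcl6 at −4.22 ± 0.40 (2.07e-06), Krt79 at −4.24 ± 0.40 (2.12e-06), Tafa1 at −5.96 ± 0.94 (0.000603) and Col23a1 at −5.49 ± 1.87 (0.0369). Col23a1 loses its call without 1003, 2001, 3001, 3003, 3005, 4003 or 4005 (adjusted p up to 0.124), Cxcl6 with an offset of 1 (−1.53, adjusted p = 0.348) and Krt79 with an offset of 64 (−0.26, adjusted p = 0.0703). Of 102 liver and 6964 spleen genes called among the 12474, 73 were called in both against 56.9 expected: 38 lower and 6 higher in both, 24 lower in liver and higher in spleen, and 5 the reverse. C1qa, Csf1r and Adgre1 fell in liver and rose in spleen (difference −1.43, −1.85 and −1.56), as did Gbp2 (−2.07) and the complement gene Cfd (−2.30), while Dhcr7 rose in liver and fell in spleen (1.53). The liver calls of Adgre1 and Gbp2 pass in only 1 of 12 refits without 1 rat (adjusted p up to 0.0932 and 0.116). Across genes, which are not independent replicates, the 2 effects had r = 0.0878. With the animals as replicate blocks (paired) 3781 genes passed, 3568 of them shared with the 4129. Of the 10 named genes Tafa1 (adjusted p = 0.0767) and Col23a1 (adjusted p = 0.128) then lost their calls. The tissue difference was not refitted with the blank division of the spleen arrays as a batch term. Its counts are therefore not corrected for that division.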

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

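The tests of the spleen wood effect, of Xist and of the pancreas transcripts were chosen only after these results were seen, and the reassignments of labels were planned.

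The wood effect in vehicle spleens, 2058 genes, coincides with the division of the spleen arrays by blanks, since every vehicle rat without wood lies on the high side. If the division were the cause, rats of a single group on its 2 sides should differ in the same genes: over 1924 of the called genes, the difference within the drug group without wood (2001 and 2003 against 2005), which holds no wood contrast, had r = 0.815 across genes with the wood contrast in vehicle, against 0.639 over all 13342 genes, which are not independent replicates, and 88.2% had the same sign. If wood acted alike under drug and gave the whole vehicle contrast, the drug-treated rats with fewer blanks should repeat it. Along the vehicle direction their median was 0.0635 (median absolute deviation 0.195) against a median size of 0.862 in vehicle. This argues against wood, acting alike, as the source of the whole contrast. The size in vehicle is not separated from the division and was taken over genes called there. A smaller wood effect, alike in both treatments, is therefore left open. A first test by sign gave 64.3%, between its bounds, and the test by size was chosen after it. Wood acting in vehicle rats alone cannot be told apart, as 0 vehicle arrays without wood have few blanks. The r and the batch term both rest on 2005 as the only array of its side outside the vehicle group, so that a peculiarity of that rat is not separated from the division; with the batch term 128 of the 2058 are still called, only 35 of them genes for which the term could be estimated.

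Xist, the RNA of the inactive X chromosome, was high in both organs of animal 2005, a rat labelled male: 10.92 in liver and 10.07 in spleen, against at most 5.51 and 5.50 in the other 11 rats. If the rat were female, male-predominant liver genes and Y-linked genes should be lowest in it, yet 2 of 8 male-predominant genes and 0 of 4 pairs of Y-linked gene and organ were lower than in every other rat, which argues against a female rat. RNA of a female mixed into the samples cannot be told: the excess over the median of the others was 5.89 in liver and 4.89 in spleen, a difference of 0.998, which the same mixing in each organ would also give. No other explanation was tested. The animal is the drug rat on the high side of the blank division, and without it 1013 genes are called for the interaction in spleen in place of 96.

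The spleen array of 2003 carried transcripts of exocrine pancreas, with Prss1 at 11.61, Pnlip at 11.38 and Cpa1 at 10.04. If pancreas tissue was taken with the spleen, the markers of the pancreas list should be highest there. Of them 100% (13 of 13) were, by a median of 4.73 (SD 1.49) over the median of the other arrays. The excess would go with pancreas tissue in the sample. It restates over the list the observation that prompted the test, and is not independent support. If the drug were the cause, the other drug spleens should show 50% or more of this excess, yet without this array their median difference from vehicle was 0.363 (SD 0.618 over the markers), which argues against the drug. The bound of this test was changed more than once after its value was seen. Prss1 was next highest in 2005 (8.22) and 1003 (7.46), a drug and a vehicle rat. Cela1 passes for the drug with and without 2003 (2.60 and 2.23). It is blank in the spleens of 1001 and 1003, so that its level in vehicle rats without wood rests on 1005 alone (5.13). Cela1 also had liver values, from 5.11 in 2003 to 8.50 in 1003.

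With reassigned labels, the drug effect in liver had as large a count in 1 of 100 splits (103 called, highest other 3). In spleen it was also 1 of 100 (7485 called, highest other 266). The real split is that 1, so no smaller share was possible with 100 splits. This argues against chance without excluding it. The tissue difference also had as large a count in 1 of 100 (4129, highest other 105). Those splits exchange drug and vehicle for both organs of a rat at once, which takes the drug effect out of each organ. They do not test the difference between the organs by itself, so nothing is concluded from them about it. For wood in spleen 2 of 100 splits gave as many (1647, highest other 1726). The higher one keeps 1001, 1003 and 1005 together, which are the vehicle rats without wood and also lie on a single side of the division by blanks, so that it does not separate wood from the division; with the batch term 108 pass, 57 of them where the term could be estimated. For the interaction in spleen 4 of 100 gave as many (96, highest other 7485, in which turning the labels of a housing yields the drug effect itself). These splits exchange drug and vehicle within each housing, so most of them mix the drug effect into the spread. Nothing is concluded from them about the interaction. In liver, wood (0 called, highest other 2) and the interaction (0, highest other 3) gave as many in 100 of 100 splits. With 0 called this share was fixed in advance and decides nothing. Within a housing or treatment 10 splits are too few for a share under 0.05: 1 of 10 for the drug without wood (liver 19, highest other 2; spleen 6140, highest other 84), 1 of 10 with wood (liver 6, highest other 1; spleen 5228, highest other 0) and 1 of 10 for wood in vehicle spleens (2058, highest other 0). For wood in vehicle livers (0, highest other 1), drug livers (0, highest other 2) and drug spleens (0, highest other 2) it was 10 of 10, again fixed by the count of 0.

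The drug effect differed between the organs in 4129 genes, a count not corrected for the division of the spleen arrays by blanks. Liver minus spleen was 8.32 for Gzmm, 7.37 for Chst1, 6.67 for Cd79b, 6.04 for RatNP-3b and 5.69 for Ahsp. It was −7.93 for Hbb, −5.96 for Tafa1, −5.49 for Col23a1, −4.24 for Krt79 and −4.22 for Cxcl6. The size for Hbb rests on liver values near the floor, Tafa1 and Col23a1 lose their calls with animals as replicate blocks (adjusted p = 0.0767 and 0.128), and Gzmm, Krt79 and Cxcl6 lose theirs with an offset (adjusted p up to 0.367, 0.0703 and 0.348). Among genes called in opposite directions it was −1.56 for Adgre1, −1.43 for C1qa, −2.30 for Cfd, −1.85 for Csf1r, 1.53 for Dhcr7 and −2.07 for Gbp2.

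The interaction in spleen called 96 genes, and the batch term could be estimated for 53 of them. It includes the wood contrast in vehicle, which coincides with the division of the spleen arrays by blanks. Its values were 1.49 for Spry2, 1.40 for Smo, 1.56 for Ppp1r14c, 1.23 for Col6a6 and 1.27 for Cbx7, of which Smo and Ppp1r14c lose their calls with the mean of their probe sets (adjusted p = 0.933 and 0.0993). They were −5.91 for Adat3, −5.09 for Papolb, −3.98 for Tmem239, −8.21 for Ranbp17 and −6.89 for Kcnk2, and these 5 calls end with each offset (adjusted p up to 0.389, 0.433, 0.823, 0.378 and 0.438).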

How the results depend on the processing

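Of 4811 comparisons of a named gene with an alternative, 4514 gave the same result, 267 a weaker, 26 a stronger and 4 a reversed one. Reversed with the mean of all probe sets were Il7 in liver (−0.42) and, in spleen, Trib3 (0.027) and Smo for wood (0.12) and for wood in vehicle (0.065), since the mean mixes probe sets that the chosen one leaves out. In the counts below, the ranges without each rat go from the lowest to the highest, alternatives with an offset, at least 2 values per group, a batch term or the 8 spleen arrays with fewer blanks were chosen after seeing the data, and the cause was not tested.

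For the drug in liver (103) genes at or above the median level gave 197, trend and robust 206, array weights 160, offset 64 195, and leaving out each rat 35–114. Without wood (19) the values were 63 at or above the median, 30 with all probe sets, 2 with only the groups compared, 42 with trend, 38 with offset 64 and 11–32. With wood (6) they were 16, 16, 1, 14 and 16, with 10 for array weights and 4–8. For wood in liver (0) leaving out each rat gave 0–1, in vehicle 0–3 with 1 for offset 64, and in drug-treated rats 0–4, with 1 each for quantile, median centring and all probe sets and 2 for offset 1. The interaction gave 0–1.

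For the drug in spleen (7485) genes at or above the median gave 4801, all probe sets 13543, a 1.5-fold change 3805 and leaving out each rat 6896–8280. Without wood (6140) all probe sets gave 10812, 1.5-fold 3981, the batch term 3794 and each rat left out 4942–7135. With wood (5228) it was 8704, 3299 and 4310–5731. For wood (1647) the median filter gave 824, all probe sets 3751, 1.5-fold 848, offsets 16 and 64 2554 and 2794, the batch term 108 and each rat left out 654–1946. In vehicle (2058) it was 847, 4769, array weights 3528, offset 64 3205, batch term 220 and 786–3277. In drug-treated rats (0) all probe sets gave 6, trend 1, array weights 1, offsets 16, 1 and 64 2, 4 and 2, the batch term 12, the 8 arrays 3 and each rat left out 0–11. For the interaction (96) the median filter gave 11, all probe sets 255, array weights 558, offsets 16 and 64 61 and 40, at least 2 values 38, the batch term 173 and each rat left out 45–1013. The tissue difference (4129) gave 6456 with all probe sets and 3488–4384. Across genes at or above the median the correlation of the drug effects in the 2 housings was 0.568 in liver and 0.909 in spleen.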

Other observations

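The batch term for the spleen arrays was chosen after seeing the data. No other test of this part was chosen after the result was seen.

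Several immune groups of the spleen have not been described. Of 6 dendritic cell genes 0 were higher and 3 lower with the drug (the same over the list alone, median −0.44), with Flt3 down by 1.10. Of 7 germinal centre genes 1 was higher and 4 lower (1 and 5 over the list alone, median −0.58), with Gcsam at −0.96. Of 11 mast cell genes 1 was higher and 2 lower (1 and 1 over the list alone, median −0.18), with Ms4a2 at −0.92. Of 15 immediate early genes 2 were higher and 8 lower (the same over the list alone, median −0.39): Nr4a1 fell by 1.76 and Myc by 1.07, while Jun rose by 1.29. Of 17 unfolded protein response genes 2 were higher and 6 lower (the same over the list alone, median −0.01, mean −0.16), with Creld2 at −1.29. Of 10 adipocyte genes 3 were higher and 4 lower (the same over the list alone, median 0.13), with Pparg at 1.45. By camera none of these lists passed, in a tissue where 7485 of all 13614 tested genes did in limma. With the division of the spleen arrays by blanks as a batch term, the lower germinal centre genes Mef2b and S1pr2 lose their calls (limma adjusted p = 0.0615 and 0.0632). So do the higher mast cell gene Gata2 (0.0919) and the lower adipocyte gene Adipoq (0.194).

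In liver, groups outside those described showed little. Of 16 T cell, 17 stroma and 6 plasma cell genes 0, 0 and 1 passed (0, 0 and 1 over the list alone). The plasma cell genes had a median of 0.10, a mean of −0.30 and a test direction of Up, as Jchain alone fell far. The bile acid enzyme Cyp7a1 stood at 1.58 ± 0.33 (limma adjusted p = 0.0657), and 0 of 16 bile acid genes passed (1 and 0 over the list alone, median 0.09). The spleen transcript of albumin, Alb, fell in the order of the animal numbers in every group. It was highest in 1001, 2001, 3001 and 4001 (9.12, 8.54, 7.78 and 8.50). The lowest values were those of 1005, 2005, 3005 and 4005 (7.43, 6.12, 5.84 and 4.88). These are given as values only.

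The spleen pattern of lost red cell, B cell and dividing-cell transcripts beside higher stroma and macrophage transcripts was measured in whole tissue. A change in cell proportions and regulation within each cell were not separated here.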
